A study of Homo sapiens with 6 samples.

How the data were processed

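RNA was measured in 6 libraries of colonies grown for 17 days from ocular surface epithelial stem cells of the human line 201B7, 3 domed and 3 flat. Per the labels' protocols, cDNA came from a full-length low-input amplification kit and was sequenced on an Illumina platform. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1, and the genome build hg19; the order of these steps, the annotation, the use of strand and the scaling option are not given in the sources used here.

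The deposited table calls its columns counts per the file headers, but its deposited values are a score, read from their low values as counts multiplied by 1 factor per library and rounded. In Flat 3 the value 5 was held by 3 genes while 4 was held by 216 and 6 by 171; in Domed 1 the value 9 was held by 2 genes while 8 was held by 122 and 10 by 105; in Domed 3 the value 4 was held by 355 genes and 5 by 131. Such gaps and doublings arise when counts are multiplied and rounded, with a best-fitting factor of 1.10 for Flat 3, 1.06 for Domed 1 and 0.892 for Domed 3. The median ratio of each library to the geometric mean of all was between 1.0038 and 1.0086. Multiplication below 1 merges neighbouring counts, so the counts were not rebuilt. The plan made before the data were examined was a quasi-likelihood test of a count model. Because the values are scaled, it was replaced by limma on log values.

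The table lists 23284 genes, of which 804 have no value in any library and were not analysed here, among them 83 genes of the lists described next. Of the 22480 others 4983 were at 0 in all libraries, and no mitochondrially encoded gene had a value. An analysis of log2(value + 1) with limma 3.58.1 in R 4.3.3 (trend and robust moderation) covered 13425 genes with a value of at least 10 in at least 3 libraries. The fold change is domed over flat on that scale, which understates the change of low genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 (two-sided). Since the read depth is unknown, a gene at 0 is said only to be listed at 0.

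A set of 41 gene lists was fixed before the data were examined, and the 33 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. With the estimated correlation no list passed (lowest adjusted p = 0.273). None passed by fry in one direction (lowest adjusted p = 0.0751), whereas 25 passed by fry for change in either direction. The limma p values of each list were also adjusted over that list alone, with no allowance for the number of lists. Of all 13425 tested genes 2149 had an unadjusted limma p under 0.05. Counts over a list alone are therefore descriptive and do not test a list. Genes were named by a rule fixed at the same time: the 8 largest log2 fold changes in each direction among called genes with a mean of at least 10 CPM (value per total of the library) and no overlap between groups, leaving out unnamed, small RNA and sex-linked marker genes; a panel of 13 genes; and up to 4 called members of each list described, or up to 2 with the lowest p where none was called. Some genes that the rule names are not reported here. Genes outside the rule are marked where they appear, except in the test of stromal cells, whose gene sets were set up after the values were seen. Reads of near-identical genes, such as the keratin, SPRR, HLA, histone and ribosomal protein families, may have been shared, so single values in those families are uncertain.

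The procedure was tested on simulated libraries, scaled and rounded in the same way, with 200 of 22480 genes changed in each of 5 runs. Means were those of the real genes, and the spread was a trend over genes of like mean, the same in both groups. Changed genes were drawn only from genes above the lowest tested means. The rates therefore need not hold for low genes or for genes whose spread differs between groups. At 1.5-fold 32.2% of changed genes were called, at 2-fold 77.3% and at 4-fold 98.2%. Of the unchanged genes that passed the filter, 66198 over the 5 runs, 0.0483% were called. Genes were simulated independently, so the tests of lists were not tried on correlated genes. Lengths and GC content came from the reference transcripts by symbol, for 85.6% of tested genes; that reference is of another genome build, so no coordinates are given.

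Alternatives were 3 planned scalings and a trimmed mean of M values, no filter and a stricter one (at least 5 CPM in at least 3 libraries), voom weights with and without sample quality weights, a replicate block, removal of the 20 most abundant genes, a threshold of 1.5-fold, and each of the 6 libraries left out in turn. Library composition was also computed over genes with at least 1 CPM in any library. Pseudocounts of 0.5 and 5 and the trimmed mean were chosen as alternatives after seeing the data, though the plan named that mean for its count model. Plots were made with matplotlib 3.10.9, and exact permutation tests and the scaling check with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.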

Results

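RNA sequencing was used to compare 2 kinds of colony formed by ocular surface epithelial stem cells. The cells came from SEAMs, the self-formed multi-zone ectodermal cultures in which eye lineages arise from human induced pluripotent stem cells, here the established line 201B7. After 17 days, 3 libraries were made from domed colonies and 3 from flat colonies, the shape having been judged by phase-contrast microscopy. Totals of the deposited values lay between 22343391 and 23298798 per library. These are library-scaled values, so the read depth of a library is unknown and no counting interval is given. The labels do not say whether the libraries of a group came from separate cultures, so every p measures only the spread between these samples, which may be technical. The cells had been seeded at either of a pair of densities, and the labels do not tie a library to one of them.

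The question was which transcripts differ between domed and flat colonies. Genes lower in domed colonies outnumbered genes higher in them: of 13425 genes tested, 221 differed by limma at a Benjamini-Hochberg adjusted p under 0.05, 71 higher and 150 lower in domed colonies. Of the lower genes 111 differed by at least 2-fold and 46 by at least 4-fold, against 50 and 19 of the higher genes. The libraries of the groups did not overlap for 2838 of the tested genes (21.1%), the 221 among them. Without ties, 10% is the mean share over all splits of the libraries into 3 and 3. The share in the other splits was not computed, so an excess over chance was not tested. The first principal component, with 36.2% of the variance, placed all domed libraries on one side and all flat libraries on the other. The count depended on single libraries: it was 71 without Domed 2, 82 without Domed 3, 79 without Flat 1 and 101 without Flat 3. It was 162 without Flat 2 and rose to 259 without Domed 1, of which 160 were among the 221. Against a threshold of 1.5-fold 26 genes passed, 6 higher and 20 lower. With sample quality weights 385 passed, 140 higher and 245 lower.

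Among the 8 genes with the largest log2 fold change lower in domed colonies and a mean of at least 10 CPM, FN1, COMP, MXRA5 and SPOCK2 encode matrix or matrix-linked proteins. FN1, which encodes fibronectin, stood at 5197 ± 939 in domed and 75242 ± 36542 in flat colonies (SD, n = 3 each), 13.3-fold lower in domed (log2 fold change -3.74, SE 0.37, adjusted p = 0.00937). COMP, a matrix glycoprotein of cartilage, was 25-fold lower (log2 fold change -4.65, SE 0.54, adjusted p = 0.00946), and MXRA5, a matrix remodelling protein, was 19.1-fold lower (log2 fold change -4.26, SE 0.31, adjusted p = 0.00325). SPOCK2, a proteoglycan, had a log2 fold change of -3.81, adjusted p 0.0196. FST, which encodes the activin antagonist follistatin, fell in the same direction at -3.60, adjusted p 0.00946, as did the proprotein convertase PCSK6 at -4.28, adjusted p 0.0306. CDKN2A, whose products inhibit the cell cycle, had the largest log2 fold change of these 8. It stood at 20, 23 and 19 in the domed libraries against 1209, 334 and 518 in the flat ones (log2 fold change -4.78, SE 0.45, adjusted p = 0.00475). MAP6, a microtubule-stabilising protein, was at -4.12, adjusted p 0.0306. The threshold was missed by CDKN2A with voom weights (adjusted p 0.0644, 0.00292 to 0.0644 over its alternatives), COMP with voom weights or sample quality weights (adjusted p 0.0666 to 0.0688, 0.00171 to 0.0688 over its alternatives) and MAP6 with voom weights (adjusted p 0.0523, 0.00439 to 0.122 over its alternatives). It was also missed by PCSK6 without Domed 3, Flat 1 or Flat 3 (adjusted p 0.0815 to 0.113), by SPOCK2 without Domed 3 or Flat 1 (adjusted p 0.0767 to 0.0812) and by MAP6 without Domed 2, Domed 3, Flat 1, Flat 2 or Flat 3 (adjusted p 0.0514 to 0.116).

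Domed colonies had more transcript of a mixed set of genes. F13A1, the catalytic subunit of a transglutaminase of blood clotting, was at 4680.3 ± 2518 in domed and 186 ± 74.9 in flat colonies (SD, n = 3 each), 23.1-fold higher (log2 fold change 4.53, SE 0.48, adjusted p = 0.00937). SEPP1, the plasma selenium carrier, was 5.46-fold higher (log2 fold change 2.45, SE 0.27, adjusted p = 0.00824), and PPP1R1B, a regulated phosphatase inhibitor, 4.08-fold higher (log2 fold change 2.03, SE 0.20, adjusted p = 0.00475). EMX2OS, the antisense transcript of the homeobox gene EMX2, was at 2.80, adjusted p 0.00475; no source used here says that the counting used strand, so its reads and those of EMX2 cannot be told apart. LPPR1 was at 2.85, adjusted p 0.0175, the phosphodiesterase PDE1C at 2.47, adjusted p 0.0129 and the kinesin KIF5C at 2.36, adjusted p 0.0179. AKR1C1, a steroid-metabolising reductase with near-identical paralogs that may share its reads, was at 2.48, adjusted p 0.0128 and is uncertain for that reason. The threshold was missed by F13A1 without Flat 1 (adjusted p 0.0656), LPPR1 without Domed 2, Domed 3 or Flat 3 (adjusted p 0.0633 to 0.0693), AKR1C1 without Domed 2 (adjusted p 0.0553), PDE1C without Domed 3 (adjusted p 0.0558) and KIF5C without Domed 2 or Domed 3 (adjusted p 0.0548 to 0.0603).

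**Figure D1:**
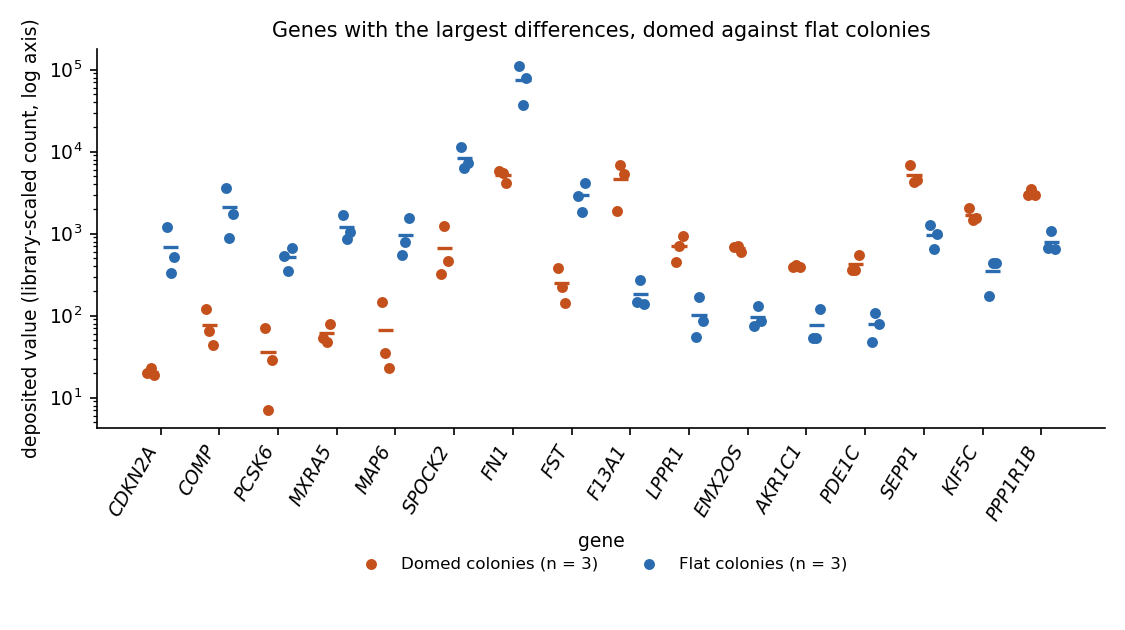
Deposited values (library-scaled counts, log axis) of the 8 genes with the largest lower and the 8 with the largest higher log2 fold change in domed colonies, among called genes with a mean of at least 10 CPM. Points are single libraries, 3 domed and 3 flat, and bars are group means. The 2 groups of points do not overlap because the genes were chosen for that.

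Both kinds of colony carried ocular surface epithelial transcripts at high level. PAX6, the eye field regulator, was at 22593 ± 2144 in domed and 18074 ± 1213 in flat colonies (SD, n = 3 each; log2 fold change 0.32, adjusted p 0.203), and TP63, the regulator of stratified epithelial stem cells, was at 0.39, adjusted p 0.202. KRT15, a keratin of basal limbal cells, was 2.92-fold higher in domed colonies (6130.3 ± 672 against 2132 ± 506; log2 fold change 1.55, SE 0.18, adjusted p = 0.00871). COL17A1, a transmembrane hemidesmosome collagen of basal cells, was 2.06-fold higher (log2 fold change 1.04, SE 0.15, adjusted p = 0.0139). The limbal basal progenitor list nevertheless went both ways: of 22 tested members 2 were higher and 3 lower. Among the lower ones were NGFR (-1.08, adjusted p 0.0194) and CPVL (-1.30, adjusted p 0.0199). Of the list 12 genes passed when adjusted over the list alone, 6 in each direction. Its camera adjusted p was 0.856. Its median of 0.00847 differed in sign from its mean of -0.14 and from the test. NGFR missed the threshold without Domed 2, Domed 3, Flat 1 or Flat 2 (adjusted p 0.0609 to 0.0837) and CPVL without Domed 2, Domed 3 or Flat 3 (adjusted p 0.063 to 0.0829).

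The corneal keratin KRT12 was abundant in both groups but spread widely, from 17625 to 70045 in domed libraries (0.50, adjusted p 0.669), and its partner KRT3 was low (1.05, adjusted p 0.366). None of 13 tested corneal genes passed over all genes, and 5 passed when adjusted over the list alone, 3 higher and 2 lower. The lowest p values belonged to the transcription factor EHF (-1.95, adjusted p 0.141) and the transketolase TKT (0.39, adjusted p 0.162). The list median was 0.39 with a camera adjusted p of 0.121, which became 0.0303 without Domed 2, 0.0319 without Domed 3 and 0.0284 without Flat 1. Of 12 conjunctival genes the mucin MUC20 was lower (-1.61, adjusted p 0.0331) and the ion transport regulator FXYD3 higher (0.68, adjusted p 0.0471). Adjusted over the list alone 5 passed. The camera adjusted p was 0.576, and the mean of -0.35 differed in sign from the median of 0.09 and from the test. Both calls were lost without any 1 of the 6 libraries (adjusted p 0.0531 to 0.134 for MUC20 and 0.0597 to 0.134 for FXYD3). So was FXYD3 with no low value filter or voom weights (adjusted p 0.0515 to 0.0628, 0.0266 to 1.0 over its alternatives). The 31 tested ocular surface transcription factors had a median of 0.28 (camera adjusted p = 7.94e-04; adjusted p = 0.273 with an estimated correlation). None of them passed over all genes and 4 passed when adjusted over the list alone, all higher in domed; the lowest p values were those of TFAP2B (0.85, adjusted p 0.0521) and SOX15 (0.81, adjusted p 0.060). The threshold was passed by TFAP2B with upper quartile scaling, stricter low value filter or pseudocount 5 (adjusted p 0.0379 to 0.0487, 0.0266 to 1.0 over its alternatives) and by SOX15 with stricter low value filter or sample quality weights (adjusted p 0.0429 to 0.0432, 0.0397 to 1.0 over its alternatives). It was also passed by TFAP2B without Domed 2 (adjusted p 0.0266) and SOX15 without Domed 3 (adjusted p 0.0406).

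**Figure D2:**
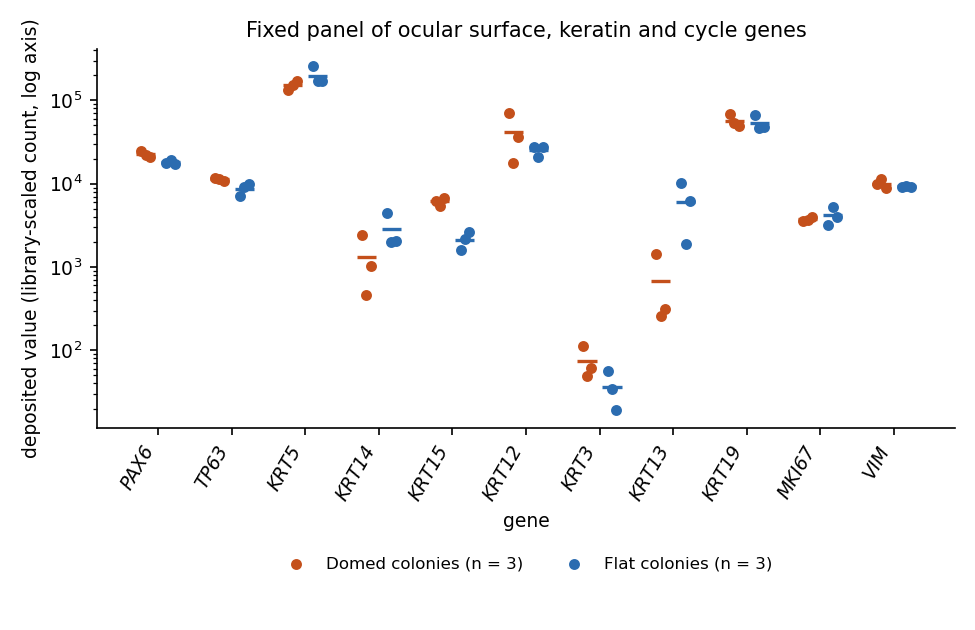
Deposited values (library-scaled counts, log axis) of the fixed panel in domed (n = 3) and flat (n = 3) colonies, with points for single libraries and bars for means. KRT15 is the panel gene that passed the threshold (adjusted p = 0.00871); GPHA2 and ABCG2 are left out because most of their values are 0.

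Among the remaining panel genes KRT5, the basal keratin, was at 153779 ± 18609 in domed and 199066 ± 49119.7 in flat colonies (SD, n = 3 each; -0.35, adjusted p 0.358), with KRT14 at -1.33, adjusted p 0.379. KRT19 (0.09, adjusted p 0.841), MKI67, the proliferation antigen (-0.13, adjusted p 0.764), and VIM, the vimentin gene (0.10, adjusted p 0.741), did not pass. The sign turned for KRT19 without Domed 1 and for MKI67 without Flat 2. KRT13, a keratin of conjunctival and mucosal epithelium, ran from 261 to 1444 in domed and from 1872 to 10077 in flat libraries and missed the threshold (-3.32, adjusted p 0.159), but passed without Flat 2 (adjusted p 0.0351). With a replicate block KRT13 (adjusted p 0.0121) and KRT14 (adjusted p 0.0458) passed. GPHA2 was listed at 0 in all 6 libraries, and ABCG2 at 0 in 5 and at 7 in Flat 3. Of the 7 tested basal and hyperproliferation keratins KRT15 alone passed over all genes and 3 passed over the list alone, 1 higher and 2 lower (camera adjusted p = 0.125). That list passed without Domed 3 (adjusted p = 0.0437) and without Flat 2 (adjusted p = 0.0395).

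The wound and mesenchymal lists were called lower in domed colonies by camera at the preset correlation. They were not called with an estimated correlation or by fry in one direction. Such camera calls also arose when libraries of the groups were mixed, as given below. Of 23 wound and migration genes 4 were lower over all genes and 11 over the list alone, with a list median of -0.84 (camera adjusted p = 8.42e-09; adjusted p = 0.273 with an estimated correlation). Besides FN1 and FST they were ITGB6, the epithelial integrin subunit of wound edges, at 1341 ± 52.5 in domed and 7534 ± 2973 in flat colonies (SD, n = 3 each; log2 fold change -2.42, SE 0.24, adjusted p = 0.00568), and the protease inhibitor SERPINE2 (-2.26, adjusted p 0.0342). Of 28 mesenchymal transition genes 3 were lower over all genes and 9 over the list alone, with a median of -0.43 (camera adjusted p = 3.57e-04; adjusted p = 0.273 with an estimated correlation). The median was -0.29 with no filter. The 3 genes were FN1, the stromal proteoglycan LUM (log2 fold change -1.84, SE 0.25, adjusted p = 0.0119) and the fibrillin FBN1 (-0.97, adjusted p 0.0434). Of the 28 genes 7 had a positive log2 fold change. Outside the naming rule, TGFBI had means of 10549 in domed and 6632 in flat colonies, and SNAI2 3536 and 3931. Also outside it, ZEB1, SNAI1, TWIST1 and TWIST2 were at 4 or below in every library and were not tested. SERPINE2 missed the threshold without Domed 3, Flat 1, Flat 2 or Flat 3 (adjusted p 0.0663 to 0.101) and FBN1 without Domed 1, Domed 2, Domed 3, Flat 1 or Flat 3 (adjusted p 0.0677 to 0.138), as did FBN1 with no low value filter or voom weights (adjusted p 0.0527 to 0.0607, 0.0298 to 1.0 over its alternatives). The marker list of neural crest cells and stromal keratocytes moved in the same direction, with 2 of 11 tested genes, LUM and NGFR, lower over all genes and 4 passing over the list alone, 1 higher and 3 lower. Its median was -0.53 (camera adjusted p = 0.0332; adjusted p = 0.273 with an estimated correlation). Its call was lost without Domed 1 (adjusted p = 0.0538), without Flat 3 (adjusted p = 0.107) and with sample quality weights (adjusted p = 0.0557). The median was -0.34 without Domed 1, -0.84 without Flat 2 and -0.33 without Flat 3. Of its 19 genes 11 also stand in another list and 6 in the mesenchymal transition list, so the 2 lists are partly the same genes.

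The TGF-beta and BMP, Wnt, Notch, and YAP and TAZ lists were called lower in domed colonies by camera at the preset correlation. None of them was called with an estimated correlation or by fry in one direction. Of 21 TGF-beta and BMP targets FST and PMEPA1 (-2.51, adjusted p 0.0342) were lower over all genes and 8 passed over the list alone, 1 higher and 7 lower (median -0.60; camera adjusted p = 6.97e-04; adjusted p = 0.273 with an estimated correlation). That median was -0.36 with the stricter filter, -0.37 without Domed 3 and -0.38 without Flat 3. Of 26 Wnt genes 4 were lower over all genes and 7 over the list alone. The 4 were the ligands WNT5A (-1.73, adjusted p 0.0194), WNT10A (-0.91, adjusted p 0.0237) and WNT7A (-1.20, adjusted p 0.0395), and FRZB, a secreted Wnt antagonist (-1.79, adjusted p 0.0294). The Wnt list median was -0.29 (camera adjusted p = 0.00438; adjusted p = 0.273 with an estimated correlation), and its call was lost without Domed 1 (adjusted p = 0.068). The Wnt median was -0.15 with the stricter filter, -0.18 without Flat 1 and -0.16 without Flat 2. Of 20 Notch genes the feedback target NRARP was lower (log2 fold change -1.17, SE 0.15, adjusted p = 0.00946) and 5 were lower over the list alone (median -0.48; camera adjusted p = 3.91e-04; adjusted p = 0.273 with an estimated correlation). Of 18 YAP and TAZ targets CCDC80 (-1.42, adjusted p 0.0493) and PTPN14 (-0.64, adjusted p 0.0495) were lower over all genes and 5 over the list alone (median -0.25; camera adjusted p = 0.00241; adjusted p = 0.424 with an estimated correlation). The YAP and TAZ median was -0.53 with sample quality weights, -0.68 without Domed 1, -0.16 without Flat 1 and -0.45 without Flat 3. Single calls were lost for PMEPA1 without Domed 2, Domed 3, Flat 1 or Flat 3 (adjusted p 0.0875 to 0.113), and WNT5A without Domed 2, Flat 2 or Flat 3 (adjusted p 0.0585 to 0.0712). They were lost for WNT10A without Domed 2, Domed 3, Flat 1 or Flat 3 (adjusted p 0.0752 to 0.0992), FRZB without Domed 2 or Domed 3 (adjusted p 0.0829 to 0.10), WNT7A and PTPN14 without any 1 of the 6 libraries (adjusted p 0.0677 to 0.142 and 0.0616 to 0.172) and CCDC80 without Domed 1, Domed 2, Domed 3, Flat 1 or Flat 3 (adjusted p 0.0656 to 0.154). Calls were also lost for PMEPA1 with voom weights (adjusted p 0.0661, 0.0131 to 0.21 over its alternatives), WNT7A with no low value filter (adjusted p 0.0534, 0.0298 to 0.669 over its alternatives), CCDC80 with trimmed mean scaling, no low value filter, voom weights, sample quality weights or pseudocount 0.5 (adjusted p 0.0505 to 0.0697, 0.019 to 0.58 over its alternatives) and PTPN14 with total scaling, no low value filter, voom weights or pseudocount 0.5 (adjusted p 0.0507 to 0.0673, 0.0319 to 1.0 over its alternatives).

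Several squamous differentiation genes were lower in domed colonies. IVL, which encodes the cornified envelope precursor involucrin, was listed at 0 in all 3 domed libraries and at 332, 35 and 149 in the flat ones (adjusted p = 0.0113). SPRR1B, another envelope precursor, was at 2 in every domed library and at 90, 75 and 355 in flat ones (log2 fold change -5.49, SE 0.71, adjusted p = 0.00946), and TGM1, the transglutaminase that joins envelope proteins, was 3.33-fold lower in domed (log2 fold change -1.74, SE 0.29, adjusted p = 0.0228). Those were the 3 of 18 tested members that passed over all genes, and 7 passed over the list alone, 2 higher and 5 lower (median -0.41; camera adjusted p = 0.00846; adjusted p = 0.424 with an estimated correlation). IVL and SPRR1B reached the lowest value tested in the 3 flat libraries alone, so they were not tested without any 1 of these or with the stricter filter. The threshold was missed by IVL with voom weights or sample quality weights (adjusted p 0.0748 to 0.116, 0.00996 to 0.116 over its alternatives), by SPRR1B with voom weights or sample quality weights (adjusted p 0.0618 to 0.138, 0.00883 to 0.138 over its alternatives), and by TGM1 without Domed 2, Domed 3, Flat 1, Flat 2 or Flat 3 (adjusted p 0.0525 to 0.0824). The list call was lost without Domed 2 (adjusted p = 0.0537), Flat 1 (adjusted p = 0.517), Flat 2 (adjusted p = 0.263) or Flat 3 (adjusted p = 0.232) and with the stricter filter (adjusted p = 0.52). The list median was -0.11 with the stricter filter, -0.22 without Flat 1, -0.22 without Flat 2 and -0.22 without Flat 3.

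Adhesion genes changed in part. The hemidesmosome and basement membrane list was lower in domed colonies (25 tested, median -0.39; camera adjusted p = 0.00106; adjusted p = 0.324 with an estimated correlation), although COL17A1, named above, was higher and the integrin subunit ITGA3 (-0.91, adjusted p 0.0482) was the one member lower over all genes. Over the list alone 11 passed, 2 higher and 9 lower. The median was -0.24 without Flat 1. Among 22 tight and gap junction genes the connexin GJB6 was 2.58-fold higher in domed (log2 fold change 1.37, SE 0.21, adjusted p = 0.0194), 3 passed over the list alone, 1 higher and 2 lower, and the camera adjusted p was 0.929. None of 17 desmosome and adherens junction genes passed either way (camera adjusted p = 0.755), the lowest p values being those of CDH3 (0.31, adjusted p 0.175) and CTNNA1 (0.30, adjusted p 0.211). ITGA3 missed the threshold without Domed 1, Domed 2, Domed 3, Flat 1 or Flat 2 (adjusted p 0.0684 to 0.155) and GJB6 without Domed 3 or Flat 1 (adjusted p 0.0644 to 0.0747). It was also missed by ITGA3 with total scaling, trimmed mean scaling, no low value filter, voom weights or pseudocount 0.5 (adjusted p 0.0504 to 0.0655, 0.0228 to 1.0 over its alternatives).

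Cell cycle genes did not separate the colonies singly. None of 36 replication genes passed, over all genes or over the list alone (camera adjusted p = 0.505), with GINS1 at -0.69, adjusted p 0.138 and RRM2 at -0.45, adjusted p 0.152, and without Flat 1 the list was called (adjusted p = 5.24e-04). None of 37 mitosis genes passed either, AURKA at -0.53, adjusted p 0.0771 and BUB1 at -0.36, adjusted p 0.195 having the lowest p values. AURKA passed in one setting, AURKA with sample quality weights (adjusted p 0.0475, 0.0475 to 1.0 over its alternatives). The list median was -0.19 (camera adjusted p = 0.00167; adjusted p = 0.724 with an estimated correlation). That call was lost without Domed 1 (adjusted p = 0.104), Flat 2 (adjusted p = 0.11) or Flat 3 (adjusted p = 0.158). The median was -0.12 without Domed 1, -0.35 without Flat 1, -0.10 without Flat 2 and -0.10 without Flat 3. Of 22 p53 targets the pro-apoptotic BAX was lower in domed (-0.95, adjusted p 0.0317) and 4 were lower over the list alone (median -0.43; camera adjusted p = 6.97e-04; adjusted p = 0.451 with an estimated correlation). That median was -0.27 without Flat 1. BAX missed the threshold without any 1 of the 6 libraries (adjusted p 0.0558 to 0.123).

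Ribosomal protein genes had positive log2 fold changes in all 64 tested members, with a median of 0.29, though none passed alone, over all genes or over the list (camera adjusted p = 3.37e-16; adjusted p = 0.476 with an estimated correlation, which was 0.892). RPL13A (0.56, adjusted p 0.0701) and RPL10 (0.51, adjusted p 0.0881) had the lowest p values. The threshold was passed by RPL13A with sample quality weights (adjusted p 0.0283, 0.0281 to 1.0 over its alternatives), by RPL10 with sample quality weights (adjusted p 0.0321, 0.0319 to 1.0 over its alternatives), and by RPL10 without Domed 1 (adjusted p 0.044). Their share of the library total was 2.56% ± 0.323 in domed and 2.04% ± 0.10 in flat colonies (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The 52 oxidative phosphorylation genes had a median of 0.07 with no member passing (camera adjusted p = 0.0332; adjusted p = 0.889 with an estimated correlation), and SDHC was at 0.38, adjusted p 0.169 and COX5B at 0.35, adjusted p 0.231. That call was lost without Domed 2, Domed 3, Flat 1 or Flat 2 (adjusted p 0.0707, 0.619, 0.31 and 0.301) and with the stricter filter (adjusted p = 0.0643). The median was 0.12 with sample quality weights, 0.14 without Domed 1, 0.01 without Domed 3, 0.04 without Flat 1 and 0.14 without Flat 3.

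**Figure D3:**
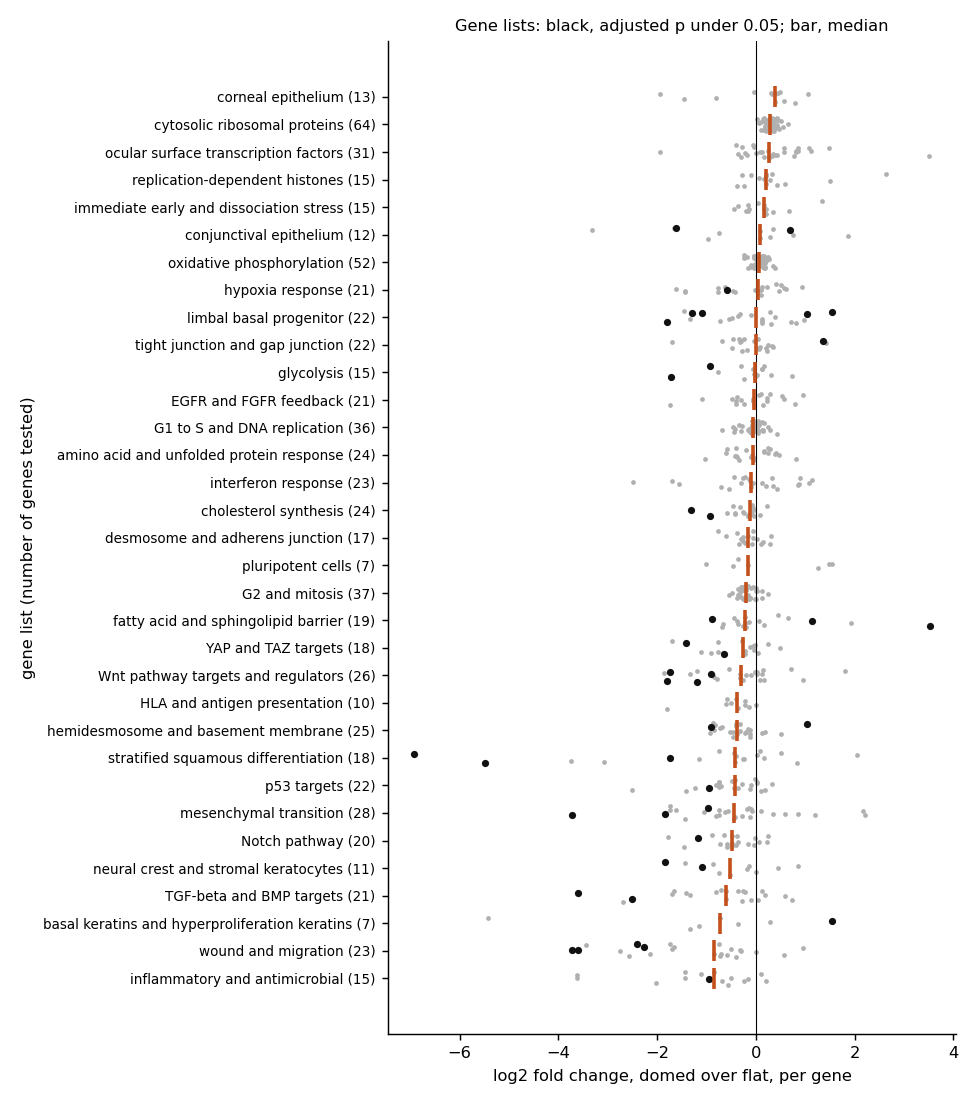
Log2 fold change, domed over flat, of every tested member of the 33 gene lists, with the number tested in brackets. Black points are genes at an adjusted p under 0.05 (limma, n = 3 against 3), grey points are the others, and orange bars are list medians, from -0.85 to 0.39.

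Markers of other cell types were mostly low. The retina list had 3 tested genes of 14 with values, the pigment cell list 2 of 12, the lens list 2 of 18, the neuron list 4 of 13, the gland list 2 of 14, the endothelium and blood list 2 of 16 and the respiratory epithelium list 1 of 10, and none of these genes passed. The abundant ones were the lens crystallin CRYAB, also widely expressed elsewhere (-2.63, adjusted p 0.0633), and the synaptic gene SYT1, at 2820 ± 403 in domed and 1829 ± 155 in flat colonies (SD, n = 3 each; 0.62, adjusted p 0.069). The threshold was passed by CRYAB with no low value filter (adjusted p 0.0417, 0.0253 to 0.316 over its alternatives) and by SYT1 with sample quality weights (adjusted p 0.0475, 0.0475 to 1.0 over its alternatives). CRYAB also passed it without Domed 1 or Flat 2 (adjusted p 0.0253 to 0.0261). The others with the lowest p values were SFRP2 (-0.80, adjusted p 0.675), CRX (-0.45, adjusted p 0.695), PMEL (0.35, adjusted p 0.776), MITF (-0.95, adjusted p 0.828), and BFSP1 (0.58, adjusted p 0.753). In the remaining lists they were INA (-1.08, adjusted p 0.176), BARX2 (2.17, adjusted p 0.0661), LYZ (-0.25, adjusted p 0.834), TEK (-1.10, adjusted p 0.358), CD68 (-0.39, adjusted p 0.868) and TPPP3 (0.37, adjusted p 0.76). Of 7 pluripotency genes none passed over all genes and 3 were higher over the list alone, with POU5F1 at 1.27, adjusted p 0.125 and SALL4 at 1.54, adjusted p 0.104 (camera adjusted p = 0.356). Its median of -0.17 differed in sign from its mean of 0.33 and from the test.

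Library composition was compared by exact two-sided permutation tests, which could not go below p = 0.1 here and so could not pass 0.05. The 20 most abundant genes took 10.4% ± 0.212 of the total in domed and 11.2% ± 0.501 in flat colonies (SD, n = 3 each; exact permutation p = 0.1). The exact permutation p was 0.4 for the total, 0.3 for the number of genes above 0, 0.9 for the histone share and 1 for the share of MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA. In Flat 1 the MTRNR2L share was 0.378%, against 0.144% to 0.197% in the other 5 libraries.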

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

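The alternatives with pseudocounts of 0.5 and 5 and the trimmed mean of M values were chosen after seeing the data. Under the 4 scalings the count of genes lay between 208 and 250, and under both pseudocounts, both filters, voom weights and removal of the 20 most abundant genes between 183 and 267. All 221 genes kept their direction wherever they were tested. Their libraries did not overlap between groups, so leaving out a library could not have turned a direction. For those fits the kept direction decides nothing. With sample quality weights the count was 385 (140 higher, 245 lower), of which 210 were among the 221. Against a threshold of 1.5-fold, a stricter question by construction, 26 genes passed (6 higher, 20 lower), all among the 221. The cause of the rise with quality weights was not tested. Leaving out 1 library at a time, with fewer samples by construction, gave 71 to 259 genes, 19 to 61 higher and 50 to 198 lower, and the lowest count shared 67 genes with the 221. Of 49 called named genes 14 were tested and passed whichever library was left out, and 2 (IVL and SPRR1B) were not tested without a flat library. None of the 49 changed direction in any alternative, which was likewise fixed for the fits with a library left out. Of 17 called lists 11 passed whichever library was left out. The threshold of 1.5-fold ended 37 of the 49 calls and voom weights 13.

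Whether replicate numbers shared by the groups pair the samples stays open. The labels state no pairing, and in the flat group their other sample codes do not follow the order of the replicate numbers. The correlation of deviations between the same numbers was 0.112, 0.0178 and 0.0475. Domed 2 and Flat 2 did not correlate best with their own number, while the other libraries did. For Flat 2 the correlation was 0.0178 with Domed 2 and 0.0179 with Domed 3. With a replicate block 463 genes were called (153 higher, 310 lower), 208 of them among the 221, and 19 lists. Among the named genes the block ended 5 calls and added 11, and among lists it added 2. The ended calls were MAP6, SPOCK2, GJB6, FRZB and ALOX15B (adjusted p 0.0508 to 0.0777). The added ones were KRT13, KRT14, SPRED1, PDIA4, VLDLR, RPL13A, RPL10, POU5F1, BARX2, TFAP2B and SOX15 (adjusted p 0.0121 to 0.0476). The added lists were corneal epithelium (camera adjusted p = 0.0347) and basal and hyperproliferation keratins (camera adjusted p = 0.0238). The number of called lists was 17 and fell to 0 with camera's estimated correlation and to 0 with fry in one direction. The planned DESeq2 test, thinned counts and the planned automatic filter were not run, since the values are not counts.

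Some directions turned. With single libraries left out, list medians ran from -0.0991 to 0.0644 for limbal basal progenitor, -0.0765 to 0.0763 for tight junction and gap junction, -0.171 to 0.0878 for G1 to S and DNA replication, -0.0499 to 0.132 for hypoxia response, -0.0342 to 0.0948 for EGFR and FGFR feedback, -0.118 to 0.0086 for amino acid and unfolded protein response, -0.489 to 0.588 for pluripotent cells, -0.248 to 0.0631 for desmosome and adherens junction, -0.0789 to 0.0228 for glycolysis, -0.0262 to 0.285 for replication-dependent histones and -0.259 to 0.11 for interferon response. Log2 fold changes ran from -0.0411 to 0.254 for KRT19, -2.58 to 0.217 for MITF, -0.661 to 0.032 for CD68, -0.0915 to 0.641 for PMEL, -0.31 to 0.054 for MKI67, -1.42 to 0.137 for SFRP2, -0.129 to 0.712 for TPPP3 and -0.203 to 1.2 for BFSP1. The median for tight junction and gap junction was 0.00386 with upper quartile and 0.0171 with total scaling, and with no filter it was -0.0984 for limbal basal progenitor and 0.0139 for EGFR and FGFR feedback. None of these genes or lists was called with all libraries, and the cause was not tested.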

Other observations

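Single genes of lipid and sugar metabolism differed between the colonies. HMGCS1, an early enzyme of cholesterol synthesis, was at 3085 ± 47.8 in domed and 5958 ± 962 in flat colonies (SD, n = 3 each; log2 fold change -0.94, SE 0.13, adjusted p = 0.0129). Of 24 cholesterol synthesis genes 2 were lower over all genes, with 3 lower over the list alone (median -0.12; camera adjusted p = 0.00138; adjusted p = 0.273 with an estimated correlation). SLC2A3, a glucose transporter, was 3.3-fold lower in domed (log2 fold change -1.72, SE 0.25, adjusted p = 0.0145) and SLC16A1, a lactate transporter, was at -0.92, adjusted p 0.0346; of 15 glycolysis genes 4 passed over the list alone, 1 higher and 3 lower (camera adjusted p = 0.309). In the fatty acid and sphingolipid list SPTLC3 (1.14, adjusted p 0.0286) and the lipoxygenase ALOX15B (3.54, adjusted p 0.0462) were higher and the desaturase FADS1 lower (-0.89, adjusted p 0.0215), 6 of 19 passed over the list alone, and the median of -0.22 and mean of 0.17 differed in sign (camera adjusted p = 0.755). P4HA2, a collagen prolyl hydroxylase, was lower (-0.58, adjusted p 0.0395) among 21 hypoxia genes, of which 6 passed over the list alone (camera adjusted p = 0.929; median 0.04, mean -0.19). The hypoxia median differed in sign from the mean and the test. Calls were lost for HMGCS1 without Domed 2 (adjusted p 0.0608), SLC2A3 without Domed 3 (adjusted p 0.0558), SLC16A1 without any 1 of the 6 libraries (adjusted p 0.0537 to 0.123), SPTLC3 without Domed 2, Domed 3, Flat 2 or Flat 3 (adjusted p 0.080 to 0.108), and ALOX15B without Domed 2, Domed 3, Flat 1, Flat 2 or Flat 3 (adjusted p 0.0598 to 0.143). They were lost for FADS1 without Domed 2, Domed 3, Flat 1 or Flat 2 (adjusted p 0.0663 to 0.0881) and P4HA2 without Domed 1, Domed 2, Domed 3, Flat 1 or Flat 3 (adjusted p 0.063 to 0.153), and for P4HA2 with no low value filter (adjusted p 0.0512, 0.0228 to 1.0 over its alternatives) and ALOX15B with no low value filter, voom weights, sample quality weights or pseudocount 0.5 (adjusted p 0.0504 to 0.0982, 0.0332 to 0.21 over its alternatives).

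The inflammatory and antimicrobial list was lower in domed colonies (15 tested, median -0.85; camera adjusted p = 0.00148; adjusted p = 0.424 with an estimated correlation), with TNFAIP3, an inhibitor of NF-kB signalling, lower over all genes (-0.95, adjusted p 0.0469) and 2 lower over the list alone. The list median was -0.40 without Domed 3, -1.57 without Flat 1 and -0.56 without Flat 3. TNFAIP3 missed the threshold without Domed 2, Domed 3, Flat 1, Flat 2 or Flat 3 (adjusted p 0.0845 to 0.139), as did TNFAIP3 with total scaling, no low value filter or voom weights (adjusted p 0.0515 to 0.0628, 0.0269 to 1.0 over its alternatives). None of 10 antigen presentation genes passed either way, the peptide transporter gene TAP1 being at -0.58, adjusted p 0.212, and the list median was -0.38 (camera adjusted p = 0.0201; adjusted p = 0.273 with an estimated correlation). That call was lost without Domed 3 (adjusted p = 0.0677), without Flat 2 (adjusted p = 0.0991) and with the stricter filter (adjusted p = 0.055). Lists with no gene past the threshold and no call were interferon response (camera adjusted p = 0.807; IFIT3 -2.48, adjusted p 0.154; IFITM1 0.86, adjusted p 0.159) and EGFR and FGFR feedback (camera adjusted p = 0.856; SPRED1 0.80, adjusted p 0.0547; SPRY4 0.95, adjusted p 0.111). The feedback list had a median of -0.04 and a mean of -0.06, opposite in sign to its test, and the threshold was passed by SPRED1 with upper quartile scaling, stricter low value filter or pseudocount 5 (adjusted p 0.0391 to 0.0495, 0.0391 to 1.0 over its alternatives). Likewise no gene passed and no call was made for immediate early and dissociation stress (camera adjusted p = 0.412; DUSP1 0.67, adjusted p 0.172; NR4A1 1.35, adjusted p 0.284), amino acid and unfolded protein response (camera adjusted p = 0.691; PDIA4 -0.61, adjusted p 0.0658; VLDLR -1.03, adjusted p 0.135) and histones (camera adjusted p = 0.231; HIST1H3D with means of 23.3 in domed and 8.67 in flat, adjusted p 0.346; HIST1H2BD 0.43, adjusted p 0.582). Over the list alone 3 feedback genes and 1 unfolded protein response gene passed, and no interferon, immediate early or histone gene.

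The tests that follow were chosen after the results were seen, except the matching of ribosomal protein genes. With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 221 genes and the highest of the other splits 0, so 1 of the 10 splits reached that count. It gave 17 lists and the highest other split also 17, so 2 of the 10 splits reached that count. Every other split called lists, from 1 to 17, while calling 0 genes. List calls by camera at the preset correlation thus also arose when the groups were mixed.

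The first pattern is the lower level of wound and mesenchymal genes in domed colonies. A single library as its source is argued against, since over the 50 tested genes of both lists the median log2 fold change was -0.66, and the value nearest 0 with a library left out was -0.50. Stromal cells mixed into the flat colonies as the source of FN1 were tested against a bound of 50% of the FN1 gain. All 8 collagen genes of the mesenchymal list with DCN and LUM together gained 7.21% of it by group means. In single flat libraries they gained -7.95% to 14.7% (unweighted mean of these 4.42%). This argues against cells that carry those transcripts in an amount like that of FN1. No stromal sample gave the ratio to expect, so it does not reach other stromal cells. The test was run in 3 forms, which like the bound were set up after the values were seen. A set of 5 genes (COL1A1, COL1A2, COL3A1, DCN and VIM) gained 2.89% by group means (-17.8% to 11% in single flat libraries). All 32 other mesenchymal transition genes gained 47.8% (-13.9% to 77.5%), past the bound in Flat 3. That sum was carried mostly by SPARC, with a mean of 88821 in domed and 109326 in flat colonies, and decided nothing. Cells rich in FN1 but poor in collagen, stromal cells as a source of the other genes (the neural crest and stromal keratocyte list had a median of -0.53) and a difference of epithelial state, not tested, may each contribute and stay open.

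The second pattern is the level of CDKN2A. Its log2 fold change with a library left out was at nearest -4.27. The gene was chosen for a large change without overlap between groups, so that value could not have come near 0. It therefore decides nothing about a single library as the source. A larger share of non-cycling cells in flat colonies may accompany the CDKN2A difference, and would put replication and mitosis genes higher in domed colonies. Their median over 73 tested genes was -0.109, from -0.291 to 0.0106 with a library left out. With all libraries the sign was opposite to the one this explanation would give. It was not stable with a library left out, so the explanation stays open. A difference tied to colony shape itself stays open too and was not tested.

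The third pattern is the shift of ribosomal protein genes. Transcript length, GC content and abundance are argued against as its whole cause: random genes matched on all 3 had a median log2 fold change of 0.0388, with 95% of 10000 draws between -0.0206 and 0.102, against 0.29 for the 64 genes. Those genes vary together between libraries, so they may stand for little more than 6 values: the exact two-sided permutation p over the libraries was 0.20, and Domed 1, at -0.0679, lay below Flat 3, at -0.0513, in mean log2 deviation. Chance placing of the libraries stays open, since 3 against 3 cannot pass 0.05, and reads shared with ribosomal protein pseudogenes were not tested.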
